A study of Oryza sativa with 12 samples.

How the data were processed

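Small RNAs of rice (Oryza sativa, cultivar Nipponbare) were sequenced from 4 tissues, with 3 libraries per tissue. Per the labels, root apices were the last 250 µm of the root tip and shoot apices were leaf primordia of seedlings aged 13 to 14 days. The developing inflorescences measured 1 to 2.5 cm, and the mature leaves 60 cm. Per the labels' protocols, RNA of 16 to 28 nt was cut from a gel, a pre-adenylylated 3′ adapter and then a 5′ adapter were ligated, and the amplified products were read by pyrosequencing. The ligation needs a 5′ phosphate, which Dicer products carry. Each of the 3 libraries of a tissue received its own 3′ adapter, and the same 3 adapters were used in every tissue, so that a replicate number stands for an adapter. The labels state that read counts of known miRNAs depended strongly on the adapter and that treating the 3 libraries as replicates is a problem. Pyrosequencing measures runs of 1 base by light intensity, so errors in run length are its usual error.

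Per the file headers, the deposited catalogue lists distinct sequences of 18 to 34 nt that match at least 1 place in the rice genome, TIGR version 5, and gives for each the number of the 12 libraries in which it was present. This presence is a whole number from 1 to 12. It is not a read count, and it does not tell which libraries or tissues held the sequence. The matching tool, the number of mismatches allowed and the way adapters were trimmed are not given in the sources used here. The deposited header text also gives the mapped reads of each library, listed by tissue without replicate numbers. The value of 1 identifier column that points to an outside database was not used here.

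The tests fixed before the data were examined compared read counts between tissues and between adapters, with the adapter as a block, and set length shares, RNA classes and phased loci per tissue side by side. All of them need values per library, so none was run, and the rule that was to choose the named miRNAs and sequences from those tests could not be applied. The miRNA families, their mature sequences and the 6 lists of families had been written down before the data were examined, and every searched family of those lists is reported. All other measurements and alternatives were chosen after the data were seen, and so were the single sequences outside the families that are named. Genome positions were not used here, so no locus is given for any sequence.

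A presence of 1 to 3 libraries can come from a single tissue. Because each tissue has 3 libraries, a presence of 4 to 6 needs at least 2 tissues, 7 to 9 at least 3 tissues, and 10 to 12 all 4 tissues. In the same way, each adapter was used in 4 libraries, so a presence of 5 or more needs at least 2 adapters. Presence depends on depth and on ligation as well as on abundance, and a low presence does not show that a sequence was limited to a tissue.

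For miRNAs, 45 mature sequences of 33 families, counting the TAS3 trans-acting siRNAs as a family, were searched. A sequence was assigned to a family when it held the 16 bases from position 3 to position 18 of a mature sequence without mismatch, with a 5′ end at most 2 nt from that of the mature sequence. For 7 members of the rice-restricted list no mature sequence was at hand, and they were not searched. The mature sequences and the rRNA segments (both ends of 18S, 5.8S and 5S) were written from general knowledge, so a wrong or missing base would lower a family's presence. The family's highest presence is that of its most widely present sequence. Lists were compared with all other families by an exact permutation test of the mean highest presence, two-sided, with Benjamini-Hochberg adjustment over 6 lists.

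Duplex partners were sought within each length. A sequence counted as having a partner when the catalogue held a sequence of the same length that pairs with it perfectly and leaves 3′ overhangs of 2 nt at both ends, the geometry left by Dicer. The same search with 5′ overhangs of 2 nt gave the background, and the mean over the 10 overhangs up to 6 nt other than 3′ overhangs of 1 to 3 nt gave another. Insertion variants were sequences from which the removal of 1 internal base, unlike both its neighbours, gave another listed sequence. Adapter-derived sequences held the last 11 bases of the 5′ adapter or the first 10 of a 3′ adapter, and they were left out of the duplex and insertion searches. The reversed, complementary and reverse complementary motifs of the 5′ adapter and the reversed motifs of the 3′ adapters served as controls. Widely present sequences were grouped when they shared a word of 16 bases.

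Shares are given with Wilson 95% confidence intervals and ratios of counts with exact Clopper-Pearson intervals. Shares were compared by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 23 tests. The sequences come from the same 12 libraries, overlap one another and are not independent replicates, so intervals, floors and the p-values of Fisher's tests cover counting error only. The p-values of the list tests rest on the spread between families and leave out counting error in each family's presence. The partner search, the family search and the insertion search were tested on simulated catalogues of 20200 sequences, where they recovered 100% of 400 planted pairs, 200 family members and 200 insertions with 0 false calls. Exact matches were planted among random sequences, so this result checks the code. It does not give the rate of false calls in the catalogue, whose sequences overlap. In 400 simulated lists without a difference, the list test gave a p under 0.05 in 4.0%. Calculations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.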

Results

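The catalogue held 781885 distinct small RNA sequences from 12 libraries of 4 rice tissues, namely root apex, shoot apex, developing inflorescence and mature leaf, with 3 libraries each. The libraries held 1161516 mapped reads in all, from 62381 to 145870 per library. The sum over the 3 libraries was 363637 reads for inflorescence, 274648 for root apex, 262040 for shoot apex and 261191 for mature leaf. Distinct sequences equalled 67.3% of the mapped reads, and each presence of a sequence in a library rested on 1.34 reads on average. Each value below is the number of libraries in which a sequence was present or a share of distinct sequences, so that the tissues are not compared with one another.

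The distinct small RNAs of these rice tissues were mainly 24 nt long, the size of heterochromatic siRNAs that guide DNA methylation. Of all distinct sequences, 58.3% (95% interval 58.2 to 58.4) were 24-nt, 15.4% were 23-nt, 8.83% were 25-nt, 6.89% were 22-nt and 4.95% (4.90 to 4.99) were 21-nt, the size of most miRNAs. Most sequences, 726625 or 92.9%, were present in 1 library, and these took up at least 62.6% of the mapped reads. A further 39671 were present in 2 libraries, 9726 in 3 and 3303 in 4. The 112 sequences present in 10 to 12 libraries, and so in all 4 tissues, were 0.0143% of the catalogue, and 32 were present in all 12 libraries. The length classes differed in how far they were shared. The 24-nt class made up 57.5% of sequences in 1 library and 68.7% of those in 2 or more, while the 23-nt share went from 15.8% to 10.2% (Fisher's exact test, adjusted p = 8.42e-296) and the 25-nt share from 9.21% to 3.87%. Among the 112 sequences found in all tissues, 26 (23.2%, interval 16.4 to 31.8) were 21-nt, against a 21-nt share of 4.95% over the whole catalogue (exact test, adjusted p = 5.64e-11 against sequences in fewer libraries). The 24-nt share of these 112 was 48.2% (39.2 to 57.4), below that of sequences in fewer libraries (exact test, adjusted p = 0.0400).

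**Figure D1:**
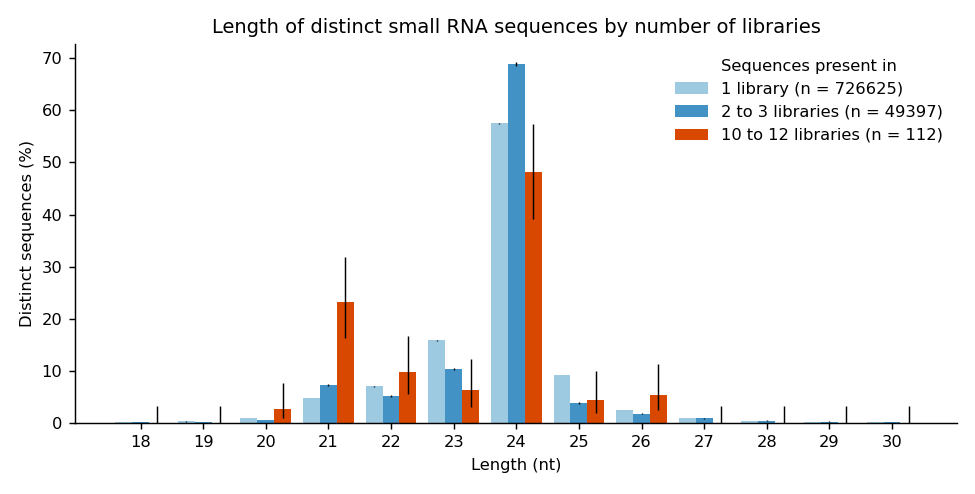
Share of distinct sequences (%) at each length from 18 to 30 nt, for sequences present in 1 library, in 2 to 3 and in 10 to 12 libraries. Bars are shares within each set and error bars are Wilson 95% intervals. The 21-nt bar reaches 23.2% among the 112 sequences in 10 to 12 libraries.

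The first nucleotide, by which Argonaute proteins select small RNAs, differed between the length classes. A stood first in 36.5% of 24-nt sequences (interval 36.3 to 36.6), U in 42.5% of 21-nt sequences and in 42.0% of 22-nt sequences. The 24-nt sequences shared by more libraries had a 5′ A more often. It opened 36.0% of the 24-nt sequences in 1 library, 41.1% of those in 2 or more (exact test, adjusted p = 1.36e-82) and 53.7% (40.6 to 66.3) of the 54 in 10 to 12. The 25-nt class went the other way, with A first in 44.7% of sequences in 1 library and in 32.7% of those in 2 or more (exact test, adjusted p = 2.01e-28). The 5′ adapter itself ends in a run of A. In all, 6494 25-nt sequences equal a listed 24-nt sequence with 1 base added at the 5′ end. That base was A in 55.2% (54.0 to 56.4). Where the base was added at the 3′ end, it was A in 26.2%. Of these extended sequences, 83.9% (5′ end) and 84.4% (3′ end) were present in 1 library. This is less than in the whole class, where 66890 of 69030 sequences were in 1 library. At 21, 22, 23, 24 and 26 nt, the base added at the 5′ end was A in 34.8%, 34.7%, 32.6%, 43.2% and 38.6%. For 21-nt sequences a difference in 5′ U between 1 library (42.4%) and 2 or more (43.5%) was not detectable (exact test, adjusted p = 0.207), whereas 5′ C opened 24.4% and 30.7% (adjusted p = 6.42e-17). Within the shared 21-nt sequences, 5′ C stood at 31.6% in 2 to 3 libraries and 20.6% (16.6 to 25.3) in 4 to 12 (exact test, adjusted p = 2.67e-05).

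**Figure D2:**
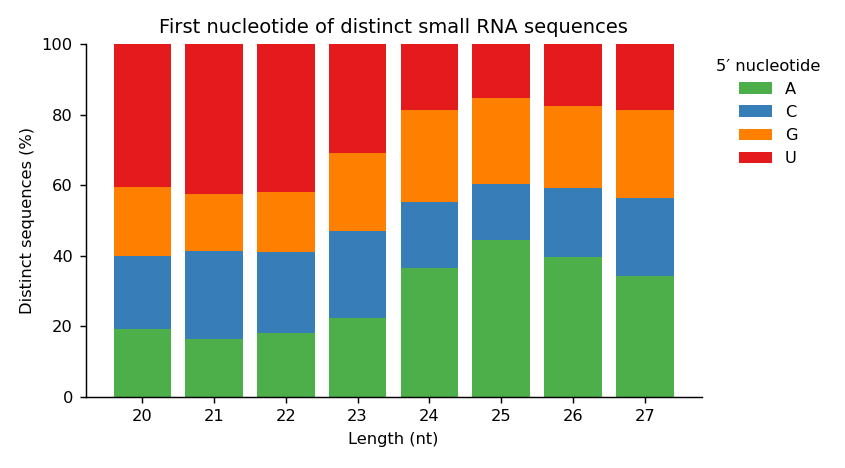
First nucleotide of all distinct sequences (%) by length from 20 to 27 nt, as stacked bars. U is the most frequent first base at 21 nt (42.5%) and A at 24 nt (36.5%).

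Known miRNAs were few among the distinct sequences but included some of the most widely present ones. Of 33 families searched, 32 had at least 1 sequence, and together they had 693 sequences, 0.0886% of the catalogue. In 11 families the most widely present sequence was found in 10 to 12 libraries: miR159, miR160, miR164, miR166, miR167, miR168, miR169, miR171, miR444, miR820 and miR1425. A further 4 families reached 7 to 9 libraries, 8 reached 4 to 6 and 9 reached 1 to 3. The mature sequences read backwards matched 0 sequences, and 1 when a mismatch was allowed.

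The 9 developmental families, whose targets include transcription factors of leaf polarity, phase change and floral identity, had a mean highest presence of 9.33 ± 2.40 libraries (SD, n = 9 families) against 5.63 ± 4.28 in the other 24 (exact permutation test, p = 0.0228), which did not pass the adjustment over 6 lists (adjusted p = 0.0684). miR159, which targets GAMYB-like factors, and miR166, which targets class III HD-ZIP factors, were present in 12 libraries each. miR164, a regulator of NAC genes, and miR171 were present in 11. miR319 and miR396 reached 9 libraries, the AP2-directed miR172 8, miR156, which targets SPL genes, 7 and miR529 5.

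The 7 families known to respond to phosphate, sulphate or copper supply were found in fewer libraries, with a mean highest presence of 2.71 ± 2.14 (n = 7) against 7.69 ± 3.97 in the other 26 (exact permutation p = 0.00392, adjusted p = 0.0235). With the listed mature sequences alone the difference was -4.30 libraries and no longer passed (adjusted p = 0.102 in the exact permutation test). miR528 was present in 6 libraries, miR397 in 5, miR408 in 3, miR395 and miR398 in 2 and the phosphate-responsive miR399 in 1. No sequence of miR827 was listed. By counting error, this allows an expected number of up to 3 among 1161516 mapped reads, if the mature sequence searched was right.

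The remaining lists did not differ detectably from the other families in exact permutation tests. In the auxin list (mean 7.00 ± 4.36, n = 5, exact permutation test, adjusted p = 0.864), miR160 and miR167, which target auxin response factors, reached 12 and 11 libraries, miR390 6, miR393 4 and the TAS3 trans-acting siRNA 2. Of the regulators of the small RNA pathway (exact permutation test, adjusted p = 0.707), the AGO1-directed miR168 was present in 12 libraries and the DCL1-directed miR162 in 6. This list and the next hold 2 families each, where even 12 libraries for both families would not have passed the test. That limit holds for high presence only and not for low presence, the side on which the next list lay. The triggers of reproductive phased siRNAs, miR2118 and miR2275, were present in 2 libraries each (exact permutation test, adjusted p = 0.341). In the list fixed as monocot- or rice-restricted, 7 families of which miR530 and miR535 are also known from other plants (mean 7.00 ± 4.58, exact permutation test, adjusted p = 0.864), miR444 and miR1425 were present in 12 libraries and miR820 in 11, against 4 for miR535 and 2 each for miR530 and miR1432. The seventh family of this list, miR528 in 6 libraries, is also in the nutrient list. Outside the lists, miR169 was present in 12 libraries and miR394 in 4.

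**Figure D3:**
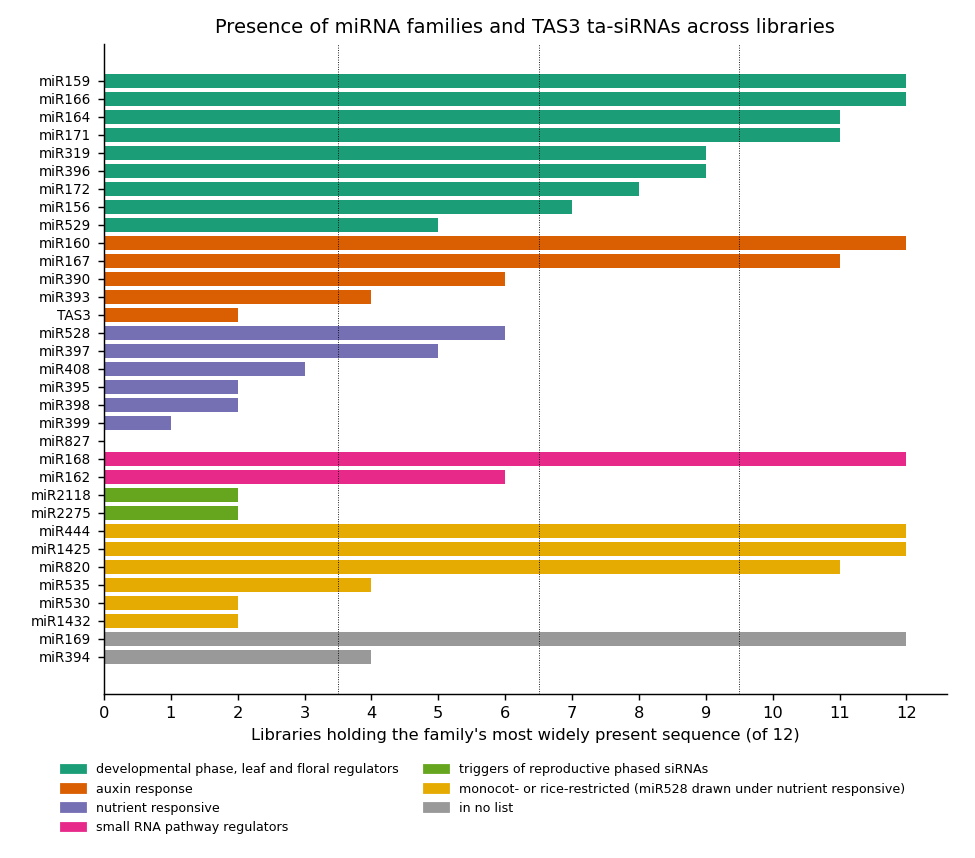
Number of libraries (of 12) that held the most widely present sequence of each family, coloured by list. Dotted lines mark the presences above which at least 2, 3 and 4 tissues are needed. The nutrient responsive families lie between 0 and 6 libraries.

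In 10 families the most widely present sequence was not the listed mature sequence. For miR820, which is encoded within transposons and targets a DNA methyltransferase, it was the 24-nt TCGGCCTCGTGGATGGACCAGGAG in 11 libraries, and 11 of the 33 miR820 sequences were 24-nt. For miR1425 it was TTAGGATTCAATCCTTGCTGC in 12 libraries, which starts 1 nt before the listed sequence TAGGATTCAATCCTTGCTGCT in 8. miR159 had the most sequences, 104, of which 45 were present in 2 or more libraries.

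The 112 sequences found in all 4 tissues mostly lay outside the searched miRNA families. They comprised 19 family members (exact test, adjusted p = 2.62e-37 against their share in sequences of fewer libraries), 7 pieces of rRNA (adjusted p = 6.22e-13), 1 adapter-derived sequence and 85 others, 50 of them 24-nt. The others still held TAGCCAAGAATGACTTGCCTA, in 12 libraries and 1 mismatch from the miR169 core, and TAGCCAAGAATGGCTTGCCTATC, in 10 libraries and 2 mismatches from it. They also held TGTTGTCTCAAGCTTGCTGCC, in 11 libraries, which shares 15 bases with the miR444 sequence TGCAGTTGTTGTCTCAAGCTT but starts beyond the limit of 2 nt, so that 19 is a lower count of family members. A 20-nt pair of exact reverse complements was among them too. The largest group of overlapping sequences had 10 members, all 24-nt, led by ACGGTGTCAAACATTTTGAAACGG in 12 libraries. The rRNA pieces included the 18S 3′ end, GGTGAACCTGCGGAAGGATCATTG, and the 5S 3′ end, TGGGAAGTCCTCGTGTTGCATCCC, each in 12 libraries. In all, 409 sequences lay within the rRNA segments searched and 171 of these were present in 2 or more libraries.

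Of the lengths from 21 to 25 nt, the 21-nt class had the strongest excess of sequences whose partner strand was also listed. Of 38579 sequences of 21 nt, 1479 (3.83%) had a partner with 2-nt 3′ overhangs, against 175 (0.454%) with 2-nt 5′ overhangs, a ratio of 8.45 (7.22 to 9.94). Both sequences of a pair are counted, but the intervals and tests on partners treat them as independent. These intervals are therefore too narrow and the p-values too small. In the 24-nt class 2.11% and 1.56% had such partners, a ratio of 1.35 (1.31 to 1.39), and in the 22-nt class 0.643% and 0.600%, a ratio of 1.07 (0.918 to 1.25). Against the mean of 10 other overhangs the excess was 7.60-fold at 21 nt but 1.13-fold at 24 nt, where overhangs of 6 nt on the 3′ side (2.33%) and the 5′ side (2.27%) had more partners. The paired 21-nt sequences opened with C in 46.5%, against 24.3% of unpaired ones (exact test, adjusted p = 7.71e-73), and with U in 13.2% against 43.6%. They were present in 2 to 3 libraries more often, 21.4% against 8.79% (exact test, adjusted p = 1.35e-46). A presence in 4 to 12 libraries was found for 15 of them (1.01%) against 0.841% of the unpaired, a difference not detectable here (exact test, adjusted p = 0.467). Of the paired sequences, 2 belonged to the miRNA families searched. The partner search required perfect pairing and the family search covered the listed mature sequences only. This count therefore does not tell how many paired sequences come from miRNA duplexes.

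**Figure D4:**
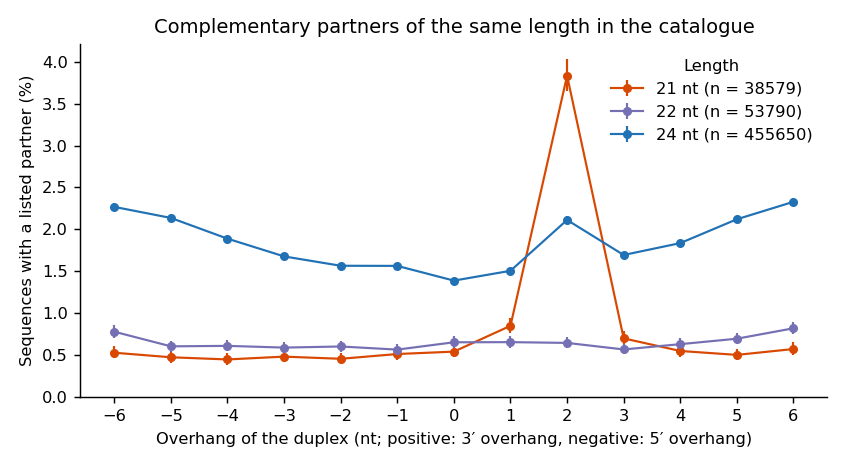
Share of 21-, 22- and 24-nt sequences (%) with a perfectly complementary partner of the same length, by the overhang the pair would leave (nt). Longer overhangs require fewer paired bases. Error bars are Wilson 95% intervals. The 21-nt share rises to 3.83% at 3′ overhangs of 2 nt.

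The number of 21-nt sequences fell more steeply between 3 and 4 libraries than that of 22-, 23- and 24-nt sequences. There were 763 in 3 libraries and 154 in 4, a ratio of 4.95 (4.16 to 5.93). The same ratio was 2.79 (2.66 to 2.93) for 24-nt sequences (exact test, adjusted p = 8.39e-11 for the difference), 2.84 for 22-nt (adjusted p = 4.56e-06) and 2.89 for 23-nt (adjusted p = 7.43e-07). At the next step, from 4 to 5 libraries, the ratio was 2.26 (1.69 to 3.06) for 21-nt and 2.66 (2.46 to 2.88) for 24-nt sequences, which did not differ detectably (exact test, adjusted p = 0.290). Among 21-nt sequences, the ratio of 3 over 4 libraries was 7.22 (4.97 to 10.8) for those with 5′ C and 4.36 (3.58 to 5.35) for those with another first base (exact test, adjusted p = 0.0229).

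**Figure D5:**
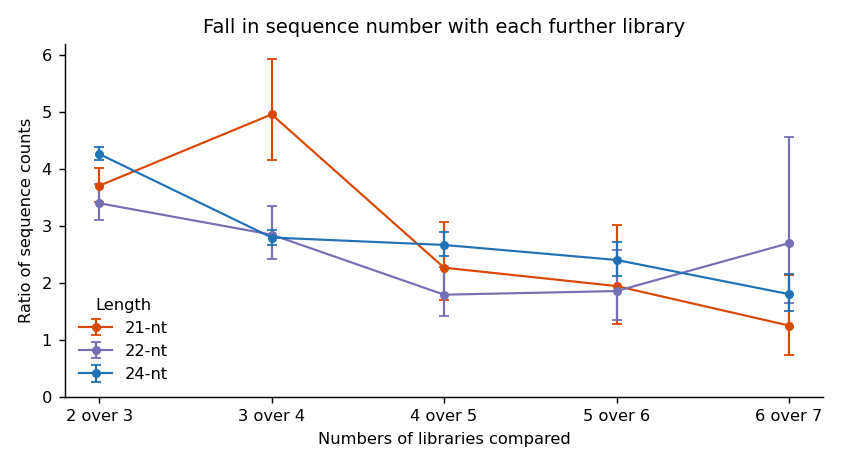
Ratio of the number of sequences in one number of libraries to that in the next, for 21-, 22- and 24-nt sequences. Error bars are exact 95% intervals. The 21-nt ratio stands at 4.95 for 3 over 4 libraries.

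A small part of the catalogue held adapter sequence. The last 11 bases of the 5′ adapter occurred in 711 sequences, and 77 of these were present in 2 or more libraries. The most widely present was TAGGCACCTGAAAACCTGAAA in 10 libraries. The same motif reversed occurred in 6 sequences and its complement in 0, while its reverse complement, the motif read on the other strand, occurred in 72. The first 10 bases of the 3′ adapters occurred in 135, 48 and 17 sequences for the adapters of replicates 1, 2 and 3, against 13, 6 and 4 for these motifs reversed. In all, 886 sequences (0.113%) were counted as adapter-derived.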

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

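All alternatives were chosen after the data were seen. Those fixed before the data were examined (other count tests, normalizations, filters, leaving out libraries or adapters, and phasing settings) act on values per library and were not run. No paired analysis was possible because the presence column carries no replicate numbers, so that neither the block nor its absence could be fitted. Of 25 alternatives for 8 results, 16 left the result on its side of the threshold or within its interval. The number of miRNA families found, which has neither, was 29 with the listed mature sequences alone, 30 without a 5′ shift and 32 with 1 mismatch, against 32. Keeping only sequences in 2 or more libraries moved the 24-nt share to 68.7%, the 21-nt share to 7.09%, the 5′ A share of 24-nt sequences to 41.1% and the excess of 21-nt partners to 5.67-fold. Keeping 20 to 26 nt gave 59.7% and 5.06% for 24 and 21 nt. Leaving out 1-base insertion variants gave a 24-nt share of 58.8% and a share in 1 library of 93.1%. These variants were 1.53% of the catalogue and adapter-derived sequences 0.113%, so leaving out either could change the shares over the catalogue only little. With the listed mature sequences alone, the nutrient responsive list lay at -4.30 libraries from the others and lost its call (adjusted p = 0.102, exact permutation), against 0.0176 with 1 mismatch allowed. The cause of these shifts was not tested. The depth was low, at 1.34 reads per presence on average, and its effect on the shares was not tested.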

Other observations

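All tests in this part were chosen after the values were seen. The CCA end, which is added to mature tRNAs, was more frequent among shared sequences of 25 and 26 nt, tested as 1 class (Fisher's exact test, adjusted p = 1.96e-31). No tRNA sequences were searched. The catalogue lists only sequences that match the genome, with an unknown number of mismatches. Whether these ends come from tRNAs was not tested. Of 26-nt sequences, 9.48% (7.80 to 11.5) of those in 2 or more libraries ended in CCA against 2.83% of those in 1 library, and of 25-nt sequences 4.39% against 2.01%. At 21 nt the shares were 2.81% (2.33 to 3.37) and 2.09% (1.94 to 2.25), and at 24 nt, where they ran the other way, 1.48% and 1.65%, neither of them tested. The same bases in another order served for comparison. ACC closed 1.02% and 1.38% of the 26-nt sequences, 1.87% and 1.92% of the 25-nt sequences, so that in 1 library it was about as frequent there as CCA, 1.10% and 1.17% of the 24-nt sequences and 0.587% and 1.01% of the 21-nt sequences. CAC closed 1.53% and 1.43% at 26 nt, 1.54% and 1.42% at 25 nt, 1.07% and 1.13% at 21 nt, and 2.30% and 2.12% at 24 nt, more than CCA.

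Among the 112 sequences present in all 4 tissues, 14 had their exact reverse complement in the catalogue. For most of them the complement was present in 1 library, as for the 21-nt miR159, miR168 and one miR169 sequence. The exception at the top was the 20-nt pair TCCCCTGTTGCGTGTCTCAG, in 12 libraries, and CTGAGACACGCAACAGGGGA, in 11. These were 2 of the 3 sequences of 20 nt in the set. Both count among the 85 sequences of no named class, and whether they are rice RNA or an oligonucleotide used in library preparation was not tested.

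Of all distinct sequences, 92.9% were present in 1 library. Whether the number of distinct sequences had levelled off at this depth was not measured directly. The Chao2 estimate was 8.80 times the number of distinct sequences listed. It is a lower bound only under equal sampling of the libraries and without erroneous sequences. The bound over the number listed was 6.07 for 21-nt, 7.37 for 24-nt and 12.1 for 22-nt sequences. The libraries were of unequal depth and adapter, so the bound describes this sampling only. The catalogue also held 11941 insertion variants and 886 adapter-derived sequences, and the bound was not computed without them. How far the bound holds for rice small RNAs was not tested.

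The fall of 21-nt sequences after 3 libraries was weighed against the adapters and against rarity. Confinement to 1 adapter would place the fall after 4 libraries if such sequences were detected in all 4 tissues. The ratio there was 2.26 (1.69 to 3.06), below the 4.95 (4.16 to 5.93) after 3. Sequences confined to 1 adapter but missed or absent in 1 tissue would reach 3 libraries at most. The ratios therefore cannot exclude the adapters. Rarity alone cannot be told apart from the pattern, because the index of the bound that equal chance in all libraries sets at 3 libraries was 0.903 (0.728 to 1.13), and a whole interval above 1 was needed to exclude it. Confinement to 1 tissue, each with 3 libraries, stays open and was not tested, since its prediction is the pattern itself.

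The 711 sequences with the end of the 5′ adapter were weighed as adapter joined to adapter or as rice RNA with the motif by chance. Chance would give the control motifs as often, and the highest of the 3, the reverse complement, occurred in 72. A first bar of 10 times the highest control was just missed, and it was replaced after the values were seen by more than 2 times beyond counting error. Adapter products that passed the genome match are a candidate source, and 25 sequences held pieces of both adapters. No biological explanation was tested.

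Insertion variants, which give a listed sequence 1 nt shorter when 1 base is removed, made up 6.74% of 25-nt sequences, 4.58% of 26-nt, 2.02% of 22-nt, 1.00% of 23-nt and 0.652% of 24-nt sequences, and these shares also depend on how many shorter sequences are listed. At 25 nt, A made up 69.3% of the 1946 insertions at positions 2 to 7 and 10.8% of the 1700 at positions 19 to 24, and U 9.25% and 72.9%, against 32.3% and 21.7% A and 21.05% and 26.2% U among all bases there. Near the 5′ end A also had the larger share at the other lengths. It made up 54.2% and 13.1% at 22 nt, 49.4% and 17.7% at 23 nt, 41.1% and 27.4% at 24 nt and 59.3% and 20.5% at 26 nt. The shares among all bases were measured at 25 nt only, so a skew beyond base composition was not shown at the other lengths. Displaced adapter bases would show A near the 5′ end, where the adapter ends in a run of A, and U near the 3′ end, where 1 of the 3 adapters starts with a run of T, so that some of these variants may, as a hypothesis, be shorter sequences with a sequencing error. Members of repeat families that differ by 1 base stay open, because neither the numbers nor the bases of the insertions at both ends, which were compared, settle what such families would show, and no biological explanation was tested.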
